A study of Mus musculus with 6 samples.

How the data were processed

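The data were RNA-seq libraries from the colon at 2 months of age, 3 from wild type mice and 3 from mice homozygous for the Lingo3 knockout. Per the protocol text shared by the 6 libraries, epithelial cells were washed off the tissue with EDTA and DTT. Total RNA was, per the labels, taken up within an hour of harvest with a Qiagen RNeasy kit. Libraries were made with a stranded TruSeq total RNA kit after Ribo-Zero Gold depletion of ribosomal RNA. The submitters' processing notes name Trimmomatic 0.39, STAR, HTSeq and DESeq2 and the genome build GRCm38. The versions of STAR, HTSeq and DESeq2, the strand setting of the counting and the release of the gene annotation are not given in the sources used here.

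The deposited count table holds raw whole-number counts per Ensembl gene for each library, which the authors made with HTSeq and did not normalise, and it ends with the HTSeq summary lines. A second deposited table gives the authors' DESeq2 comparison: the log2 fold changes and their standard errors are those of DESeq2, with positive values higher in knockout. The p-values in this deposited table, unadjusted and adjusted, are also those of DESeq2 per the file headers. Its signal columns, the normalized values per library, are deposited as the raw counts times 1 factor per library, with a largest relative deviation of 5.00e-15. The comparison table was used only descriptively. It lists 15138 genes, its log2 fold changes correlated with those of edgeR at a Pearson r of 1.00 across genes, and both come from the same libraries, so neither is independent evidence for the other.

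Gene identifiers were looked up in the GENCODE M21 annotation of GRCm38, where 45143 of 46078 (98.0%) had an entry, and symbols in the gene lists were matched through this annotation and RefSeq synonyms. The HTSeq summary lines were left out of the library sizes. They held 58.4% ± 1.74 (SD, n = 3) of all reads counted in wild type and 55.7% ± 1.85 (SD, n = 3) in knockout. Reads outside any annotated feature made 20.5% ± 1.85 and 21.7% ± 2.15 (SD, n = 3), reads without a unique alignment 36.7% ± 0.184 and 32.6% ± 0.309 (SD, n = 3), and ambiguous reads 1.23 to 1.57% per library. Counts over genes ran from 11868000 in knockout replicate 3 to 28029583 in wild type replicate 2. A floor of 3 counts, below which a gene was treated as not measurable, corresponded to 0.113 to 0.240 CPM. The libraries carry no molecular identifiers, so floors and 95% intervals cover counting error only. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of at least 9.40, so none is a copy of another.

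Genotype was the only term of the model, with wild type as reference. Genes were kept by filterByExpr with a minimum count of 10 in enough libraries and a minimum total of 15, scaled with TMM factors and tested with edgeR's robust quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment over the 16856 genes kept and a threshold of 0.05. Fold changes are knockout minus wild type on the log2 scale, and log2 CPM used a prior count of 2. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 38 lists with 5 or more tested members, beside camera with an estimated correlation and fry. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Shares of counts were compared with an exact permutation test.

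The test, the lists, the alternatives named first below and the rule for naming genes were fixed before the data were examined. The rule named Lingo3, the single genes Tff1, Tff2, Tff3, Lgr5, Muc2, Mki67 and Egfr, and members of each list. It also named the 12 largest changes in each direction among genes with an adjusted p under 0.05, a mean CPM of at least 1, groups that did not overlap and an established symbol, which left 1537 candidates higher and 830 lower. Not every list member past the threshold is named: the examples were chosen among them after their values and the fits without single libraries were seen, and they lean towards genes whose call was kept. The pan-epithelial, GIMAP and other lists of the closing section were chosen after the data were seen.

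The fixed alternatives were RLE, upper-quartile or no composition factors, DESeq2 or limma-voom in place of edgeR, no filter, a mean CPM of at least 1, the replicate number as a block, each library left out in turn, an adjusted p under 0.1 and glmTreat against a 1.2-fold change. Those added after the data were seen were counts thinned to the smallest total, offsets for GC content and length of the longest transcript, nuclear protein-coding genes only, and upper-quartile factors for the list tests.

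The methods were tested on simulated counts for 16856 genes in 6 libraries, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. With the dispersion estimated for each gene, edgeR found 37.3%, 79.1% and 92.4% of these, and 24 of its 163 calls (14.7%) were false, 21 of them in the decile of genes with the highest dispersion relative to the trend. The false share exceeded a bound of 10% that had been set for this test, and was 19.0% with DESeq2 and 11.6% with limma-voom. With dispersions on the fitted trend, edgeR found 41.8%, 83.6% and 97.0%, and 4 of 152 calls (2.63%) were false, against 2.00% with DESeq2 and 2.61% with limma-voom. A simulated list raised 1.5-fold was found by all 3 list tests. The adjusted p was 4.78e-40 with camera's preset correlation, 0.00427 with camera's estimated correlation and 0.000411 with fry. With no change 0 lists passed any of the 3. The simulated genes were drawn independently, so these results do not cover lists whose genes vary together. The simulation also changed far fewer genes than the 2596 called in the data and gave the other genes the same mean level in both groups. Its shares of false calls therefore need not hold for the real calls. In the real lists the estimated correlation ran from -0.094 (LINGO family) to 0.84 (red blood cells).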

Results

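RNA was sequenced from the epithelial fraction washed from the colon of 2-month-old mice that were either wild type or homozygous for a knockout of Lingo3, with 3 libraries per genotype and 6 in all. Lingo3 encodes a transmembrane protein with leucine-rich repeats and an immunoglobulin domain. The libraries were made from total RNA after depletion of ribosomal RNA, and the values used were raw read counts per gene. Counts over genes reached 25010618, 28029583 and 25151356 in wild type replicates 1, 2 and 3 and 17200931, 16762320 and 11868000 in knockout replicates 1, 2 and 3, so that the wild type libraries were the deeper ones. Transcripts of the mitochondrial genome took 46.8% ± 1.60 (SD, n = 3) of the counts in wild type and 35.5% ± 0.823 (SD, n = 3) in knockout. Most of this share was mitochondrial ribosomal RNA, with 33.25% ± 1.34 (SD, n = 3) of the counts in wild type and 24.96% ± 0.248 (SD, n = 3) in knockout. The mitochondrial gene mt-Co1 took 11.5% ± 0.882 (SD, n = 3) and 8.75% ± 0.704 (SD, n = 3). Nuclear protein-coding genes took 46.2% ± 0.670 (SD, n = 3) and 58.7% ± 0.403 (SD, n = 3). For depth and for each of these shares the groups did not overlap. The 2-sided exact permutation p was 0.1 for each, the smallest that 3 against 3 libraries can give. Pairwise correlations of log2 CPM (counts scaled to a common library size) across genes lay between 0.967 and 0.987, and the first principal component, with 48.6% of the variance, separated the genotypes. The label of wild type replicate 1 names a wash with both EDTA and DTT, and the labels of the other 5 libraries name EDTA alone, while the protocol text shared by all 6 names both. The labels do not say whether the libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical.

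**Figure D1:**
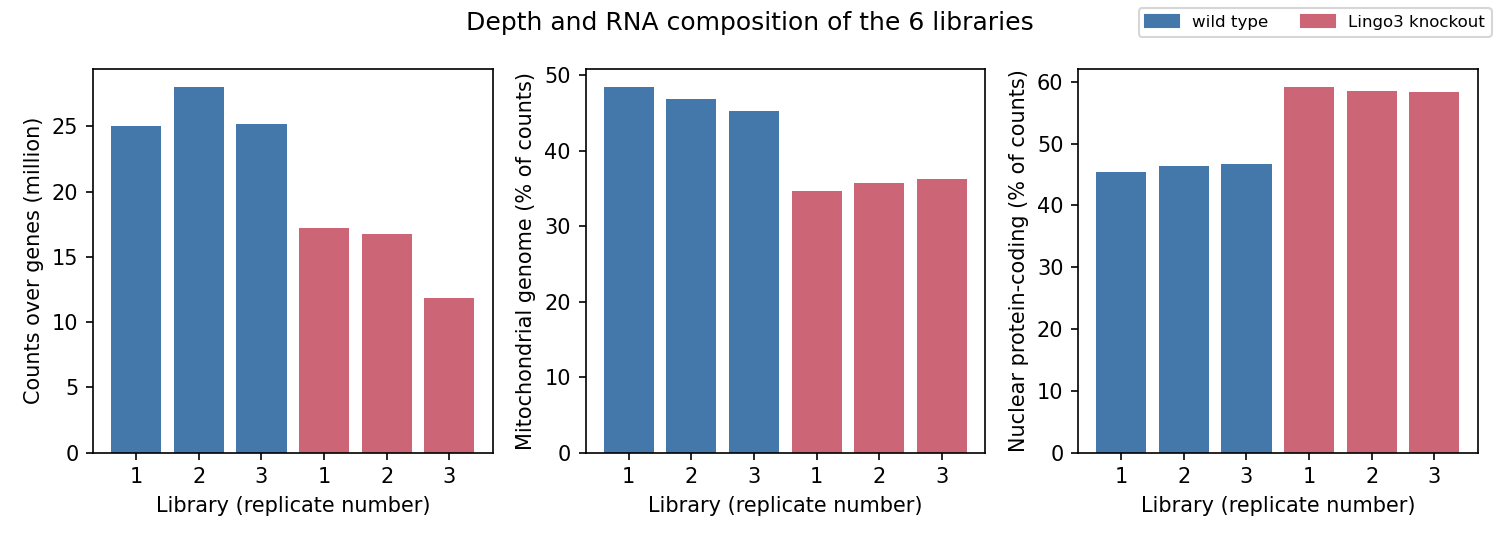
Depth and RNA composition of each library, with replicate number on the horizontal axis, wild type in blue and Lingo3 knockout in red. The bars give counts over genes, the percentage of counts from the mitochondrial genome and the percentage from nuclear protein-coding genes; the knockout libraries held 11868000 to 17200931 counts and the wild type libraries 25010618 to 28029583.

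The targeted gene was at the limit of detection in both genotypes. Lingo3 lies on chromosome 10 from 80832801 to 80844039 on the minus strand of GRCm38. It had 3, 3 and 1 counts in wild type replicates 1, 2 and 3 and 2, 0 and 1 counts in knockout replicates 1, 2 and 3. The mean was 0.0989 ± 0.050 CPM (SD, n = 3) in wild type and 0.0610 ± 0.0541 CPM (SD, n = 3) in knockout, and a floor of 3 counts corresponded to 0.113 to 0.240 CPM per library. A difference was not detectable at this depth, no fold change is given, and the gene does not check the genotype labels. With no filter on low counts the adjusted p was 0.765 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

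The comparison of knockout with wild type asked which transcripts of the colon epithelial fraction differ when Lingo3 is deleted. In the knockout libraries 20 of 30 cell cycle genes, 8 of 16 stem cell genes and 9 of 23 goblet cell genes rose, with 0 falling in each list. Of 27 T cell and intraepithelial lymphocyte genes 23 fell, and of 20 B cell and plasma cell genes 8 fell, with 0 higher in either list. Of 25 immediate early and heat shock genes 9 were lower and 1 higher, and 5 of 9 tested mitochondrially encoded genes were lower, whereas 18 of 45 nuclear genes of oxidative phosphorylation were higher. Of 16856 genes tested, 2596 changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1589 higher and 1007 lower (61.2% higher). Most changes were modest, with a median absolute log2 fold change of 0.59, and 83 genes rose and 373 fell by more than 2-fold. Among protein-coding genes 1557 rose and 868 fell, and among other gene types 32 rose and 139 fell.

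The split of calls depended on how the libraries were scaled. With upper-quartile factors 1137 genes rose and 1365 fell (45.4% higher), and with library totals only 5415 rose and 420 fell (92.8% higher), a scaling that raised the median log2 fold change of all genes by 0.28. The counts per list moved as well. The cell cycle genes that rose were 10 without wild type replicate 3, 11 without knockout replicate 2 and 12 without knockout replicate 3. The B cell and plasma cell genes that fell were 15 without wild type replicate 1, 3 without wild type replicate 2, 5 without knockout replicate 1 and 1 without knockout replicate 2 or 3. The mitochondrially encoded genes that fell were 3 without wild type replicate 1 or 2 and 2 without any 1 of the knockout replicates 1, 2 and 3, and the oxidative phosphorylation genes that rose were 9 without knockout replicate 3, where 1 fell. Without knockout replicate 2, 4 immediate early and heat shock genes were lower, and without wild type replicate 1, 2 were higher. The number of changed genes was 1672 without wild type replicate 2 (581 lower), 1679 without wild type replicate 3 (936 higher), 1371 without knockout replicate 2 (898 higher, 473 lower) and 1124 without knockout replicate 3 (711 higher, 413 lower). The authors' deposited table, made with DESeq2, held 2531 genes under an adjusted p of 0.05, 1514 higher and 1017 lower, of which 2225 were also called here, all in the same direction.

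The gene with the largest fitted change among those past the threshold was Hist1h4m (ENSMUSG00000069306), a histone H4 gene on chromosome 13 from 21811746 to 21812147. It had 179, 198 and 202 counts in wild type replicates 1, 2 and 3 and 1 count in each knockout library. Its level in knockout was 0.724% of the wild type level, with a 95% counting interval of 0.149 to 2.13%; the reads of such near-identical histone genes could be split between copies, so the value is uncertain. Syngr3 (ENSMUSG00000007021), which encodes the synaptic vesicle protein synaptogyrin 3 and lies on chromosome 17 from 24685092 to 24689955, rose from 0.402 ± 0.150 to 6.30 ± 2.21 CPM (SD, n = 3), a log2 fold change of 3.95 ± 0.35 (SE; edgeR adjusted p = 0.000741). Il1b (ENSMUSG00000027398) is the gene of the cytokine interleukin 1 beta on chromosome 2 from 129364570 to 129371139. Its level fell from 2.20 ± 0.134 to 0.167 ± 0.131 CPM (SD, n = 3), a log2 fold change of -3.60 ± 0.41 (SE, edgeR adjusted p = 0.000785). The knockout mean of Il1b lay at the floor of 3 counts, which was 0.154 to 0.240 CPM in the knockout libraries, so the size of this fall is uncertain. Among genes past the threshold with an established symbol, a mean CPM of at least 1 and groups that did not overlap, the others of the 12 largest increases were in Itln1, an intelectin that binds microbial glycans (log2 fold change 1.89), Cd177 (1.79), the stem cell transcription factor Ascl2 (1.78), the Wnt receptor gene Fzd9 (1.75), Apol11b (1.69), Tmem182 (1.66), the acyl-CoA thioesterase gene Acot1 (1.52), Vsig1 (1.49), the interferon-induced GTPase gene Iigp1 (1.44), Crisp3 (1.44) and the cysteine dioxygenase gene Cdo1 (1.40). Within the same limits the others of the 12 largest decreases were in Ccn1, a secreted matricellular protein (-2.56), the T cell costimulatory receptor gene Tnfrsf9 (-2.42), the CD8 beta chain gene Cd8b1 (-2.40), Bmp4 (-2.26), the elastin gene Eln (-2.22), the B lineage transcription factor Pax5 (-2.16), Ifi208 (-2.14), Cd4 (-2.08), Fosb (-2.05) and Efs (-2.05). Of these genes, 5 lost their call without single libraries. Apol11b lost it without wild type replicates 2 or 3 or knockout replicates 1 or 2 (highest edgeR adjusted p = 0.0663), and Vsig1 without wild type replicates 2 or 3 or knockout replicates 2 or 3 (0.0770). Ccn1 lost it without any 1 of the knockout replicates 1, 2 and 3 (highest edgeR adjusted p = 0.161), Bmp4 without knockout replicates 2 or 3 (0.0662), and Fosb without wild type replicate 2 or any 1 of the knockout replicates (0.154).

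Of the gene lists fixed before the data were examined, 38 had 5 or more tested members, and 19 of these passed the camera test with a preset correlation between genes of 0.01. With an estimated correlation 0 of the 38 passed (smallest camera adjusted p = 0.450, with 2 at an unadjusted p under 0.05). By fry, a test of whether a list's genes move on balance in 1 direction, 6 passed. These were the stem cell, goblet cell, mucin O-glycosylation, Wnt target, mitochondrially encoded and T cell lists. The cell cycle (fry adjusted p = 0.0614), immediate early and heat shock (0.105), B cell (0.119) and nuclear oxidative phosphorylation (0.156) lists did not pass it. The preset test also passed 4 to 17 lists when the 6 libraries were divided in the 9 other ways into 3 and 3. These divisions left the genotypes unequal between the sides, so they do not measure false calls. Its p-values rest on the preset correlation and are read with caution. The counts of genes below are descriptive, since genes of a list can vary together. With DESeq2 in place of edgeR, 14 goblet cell, 11 endoplasmic reticulum stress and 4 antimicrobial genes rose, and 13 B cell and plasma cell, 14 immediate early and heat shock, 5 fibroblast, 5 xenobiotic and 4 epithelial repair genes fell. With limma-voom 5 B cell and plasma cell genes fell. In 16 of the 19 lists the call was kept without any single library.

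**Figure D2:**
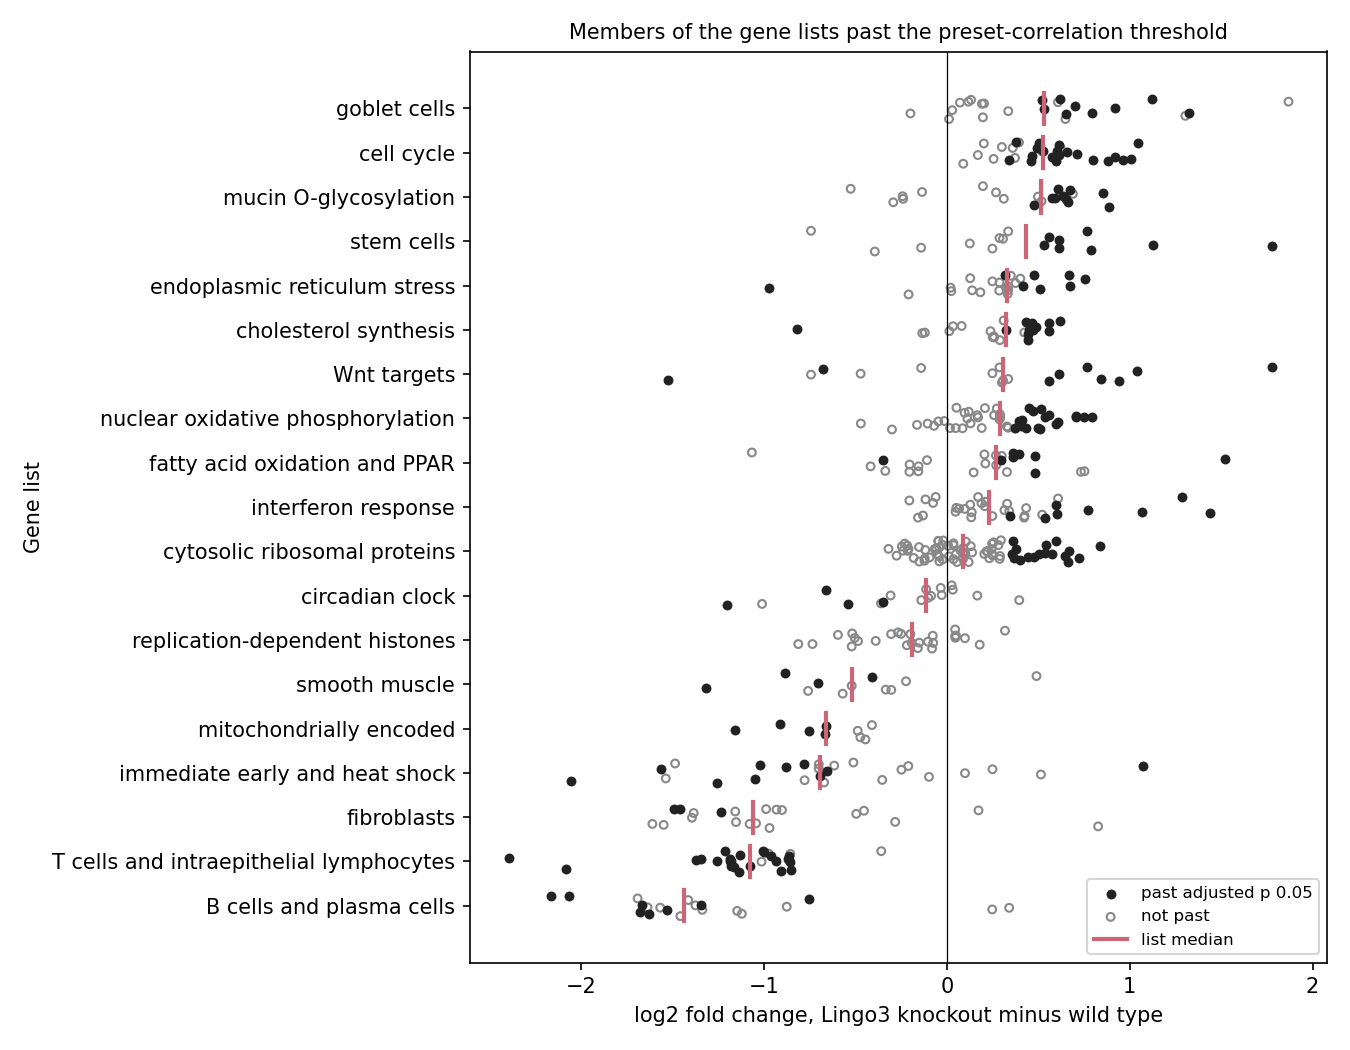
Log2 fold change of the tested members of the 19 gene lists that passed the camera test with a preset correlation, knockout minus wild type. Each point is a gene, filled where its adjusted p was under 0.05, and the red bar is the list median, which ran from -1.44 for B cells and plasma cells to 0.53 for goblet cells; with library totals only, which raised the median of all genes by 0.28, the medians of the circadian clock and histone lists turned to 0.17 and 0.09, and relative to that shift they were -0.11 and -0.19.

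The stem cell and cell cycle lists passed the camera test in the higher direction, in the same libraries in which the mean of the T cell list was lower by -1.14 ± 0.22 (SE, log2 scale). Of 16 tested stem cell genes, 8 rose, 0 fell and 8 did not pass, and adjusted over the list alone 9 rose (camera adjusted p = 5.23e-05, and adjusted p = 0.450 with an estimated correlation). The chloride cotransporter gene Slc12a2 rose from 166 ± 8.33 to 364 ± 34.0 CPM (SD, n = 3), a log2 fold change of 1.13 ± 0.11 (SE; edgeR adjusted p = 0.000785). Ascl2 rose by 1.78 and the ephrin receptor gene Ephb2 by 0.62 on the log2 scale. The stem cell marker Lgr5 passed narrowly (log2 fold change 0.56, edgeR adjusted p = 0.0447), and its call was lost without any 1 of the wild type replicates 1, 2 and 3 or knockout replicates 2 and 3 (highest adjusted p = 0.200). Of 30 tested cell cycle genes, 20 rose, 0 fell and 10 did not pass, and adjusted over the list alone 26 rose (camera adjusted p = 1.46e-12, and adjusted p = 0.450 with an estimated correlation). The cyclin A2 gene Ccna2 rose by 1.04, the replication helicase subunit gene Mcm6 by 0.80 and the topoisomerase gene Top2a by 0.71, while the proliferation marker Mki67 did not pass (0.17, edgeR adjusted p = 0.379). Of 17 Wnt target genes, which share 10 tested members with the stem cell list, 7 rose, 2 fell and 8 did not pass, and adjusted over the list alone 10 rose and 2 fell (camera adjusted p = 0.00803, and adjusted p = 0.450 with an estimated correlation). With library totals only the Wnt list lost its call (camera adjusted p = 0.118). Myc rose by 1.04 and the cyclin D1 gene Ccnd1 by 0.84, whereas Lef1 (-1.52) and Tcf7 (-0.68), transcription factors that T cells also express, fell. Tcf7 lost its call without wild type replicates 2 or 3 or knockout replicates 2 or 3 (highest edgeR adjusted p = 0.112).

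The goblet cell list and that of the enzymes that glycosylate mucins passed the camera test in the higher direction, while the list of mucins and trefoil factors did not pass with all libraries. Of 23 goblet cell genes, 9 rose, 0 fell and 14 did not pass, and adjusted over the list alone 12 rose (camera adjusted p = 1.55e-07, and adjusted p = 0.450 with an estimated correlation). The kallikrein gene Klk1 rose from 205 ± 27.6 to 513 ± 34.5 CPM (SD, n = 3), a log2 fold change of 1.33 ± 0.13 (SE; edgeR adjusted p = 0.000785). The secretory lineage transcription factors Atoh1 and Spdef rose by 0.92 and 0.70. Of 21 mucin O-glycosylation genes, 10 rose, 0 fell and 11 did not pass, and adjusted over the list alone 11 rose (camera adjusted p = 6.76e-06, and adjusted p = 0.450 with an estimated correlation). Of these genes 1 fell without wild type replicate 2 or knockout replicate 1. Galnt5 and Galnt3, whose enzymes start O-glycan chains, rose by 0.89 and 0.85. Of 11 trefoil factor and mucin genes, 0 rose and 0 fell, by edgeR over all genes, adjusted over the list alone, by DESeq2 and by limma-voom, and 2 were lower at an unadjusted p under 0.05 (list median -0.32, -0.41 to -0.12 without single libraries, camera adjusted p = 0.127). The list passed in the lower direction without wild type replicate 2 (camera adjusted p = 0.0207), and 1 member fell without wild type replicate 1 or knockout replicate 1. Muc2, the main secreted mucin of the colon, had a log2 fold change of 0.12 (edgeR adjusted p = 0.648). Tff3, the goblet cell trefoil factor, had -0.20 (edgeR adjusted p = 0.541), which turned to 0.10 with library totals only, a scaling that raised the median of all genes by 0.28. Tff2 stood at 0.778 ± 0.0557 and 0.614 ± 0.347 CPM (SD, n = 3), and Tff1 had 1 count over the 6 libraries.

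The lists of other epithelial lineages did not pass the camera test with all libraries. Of 24 absorptive colonocyte genes, 1 rose, 1 fell and 22 did not pass, and adjusted over the list alone 0 passed (median -0.21, -0.29 to -0.06 without single libraries, or 0.07 with library totals only; camera adjusted p = 0.404). The butyrate transporter gene Slc5a8 rose by 0.61 and the carbonic anhydrase gene Car4 fell by 0.68 on the log2 scale. The call of Slc5a8 was lost without wild type replicates 2 or 3 or knockout replicates 2 or 3 (highest edgeR adjusted p = 0.147), and that of Car4 without wild type replicates 1 or 3 or any 1 of the knockout replicates (0.146). Without wild type replicate 2, 7 absorptive genes fell and the list passed (camera adjusted p = 0.00649), and without wild type replicate 1, 2 rose. Of 22 enteroendocrine genes, 1 rose, 3 fell and 18 did not pass, and adjusted over the list alone 1 rose and 3 fell (median -0.32, -0.44 to -0.14 without single libraries, camera adjusted p = 0.201). Without knockout replicate 3 or any 1 of the wild type replicates, 1 enteroendocrine gene fell. With library totals only this list passed in the lower direction relative to other genes (camera adjusted p = 0.0251; mean log2 fold change 0.14). The prohormone convertase gene Pcsk1 rose by 0.70. Of 21 tuft cell genes, 4 rose, 0 fell and 17 did not pass, and adjusted over the list alone 4 rose (median 0.22, 0.12 to 0.32 without single libraries, camera adjusted p = 0.0565). Without wild type replicate 2 or 3 or knockout replicate 1 or 2, 2 tuft cell genes rose, and without wild type replicate 3, 1 fell. The tuft cell list passed without wild type replicate 1 (camera adjusted p = 0.0472), wild type replicate 2 (0.0342) or knockout replicate 3 (0.00916), with upper-quartile factors (0.0397) and with the replicate number as a block (0.0474). Cd24a, which other epithelial cells also express, rose by 0.92. Of 20 small intestinal enterocyte genes, 1 rose, 1 fell and 18 did not pass, and adjusted over the list alone 1 rose and 1 fell (median -0.05, -0.051 to 0.30 without single libraries, or 0.23 with library totals only; mean -0.04, camera direction higher, adjusted p = 0.886). In this enterocyte list 2 genes fell without wild type replicate 2 or knockout replicate 1. The peptidase gene Enpep fell by 0.90 and the glucose transporter gene Slc5a1 rose by 0.49, a call lost without wild type replicates 2 or 3 or knockout replicates 2 or 3 (highest edgeR adjusted p = 0.130). Of 10 posterior Hox genes, 0 passed over all genes, adjusted over the list alone, by DESeq2, by limma-voom or at an unadjusted p under 0.05 (median 0.25, 0.19 to 0.43 without single libraries, camera adjusted p = 0.159). The Hox list passed without wild type replicate 1 (camera adjusted p = 0.0309) or knockout replicate 1 (0.0149), and 1 Hox gene rose in each of these fits.

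Both lymphocyte lists passed the camera test in the lower direction. Of 27 T cell and intraepithelial lymphocyte genes, 0 rose, 23 fell and 4 did not pass, and adjusted over the list alone all 27 fell (median -1.08, camera adjusted p = 7.44e-18, and adjusted p = 0.450 with an estimated correlation). Cd8b1 fell from 7.38 ± 1.72 to 1.39 ± 0.346 CPM (SD, n = 3), a log2 fold change of -2.40 ± 0.25 (SE; edgeR adjusted p = 0.000785). The granzyme B gene Gzmb (log2 fold change -1.37) and the pan-leukocyte gene Ptprc (-0.86) fell as well, and the T cell receptor component gene Cd3e fell from 13.8 ± 1.54 to 6.91 ± 1.91 CPM (SD, n = 3). Of 20 B cell and plasma cell genes, 0 rose, 8 fell and 12 did not pass, and adjusted over the list alone 16 fell (median -1.44, camera adjusted p = 2.41e-06, and adjusted p = 0.450 with an estimated correlation). The median of this list was -0.89 without wild type replicate 2. Its genes that fell were 13 by DESeq2 and 5 by limma-voom. Pax5 (-2.16) and Cd79b (-1.67), a subunit of the B cell receptor, fell, and the call of Cd79b was lost without knockout replicates 2 or 3 (highest edgeR adjusted p = 0.0650). Of 18 macrophage, dendritic cell and granulocyte genes, 1 rose, 3 fell and 14 did not pass, and adjusted over the list alone 1 rose and 4 fell (median -0.26, -0.52 to -0.047 without single libraries, or 0.03 with library totals only; mean -0.01, camera adjusted p = 0.404). Cd14, the endotoxin coreceptor gene, rose by 1.00, and the chemokine receptor gene Ccr2 fell by 1.02, a call lost without wild type replicate 3 or knockout replicates 2 or 3 (highest edgeR adjusted p = 0.0758). Of 20 cytokine and chemokine genes, 2 rose, 6 fell and 12 did not pass, and adjusted over the list alone 2 rose and 7 fell (median -0.14, -0.40 to -0.10 without single libraries, or 0.15 with library totals only; camera adjusted p = 0.139). The cytokine and chemokine genes that fell were 2 without wild type replicate 2 or knockout replicate 3 and 3 without wild type replicate 3 or knockout replicate 2, and those that rose were 1 without knockout replicate 2 or 3. With library totals only this list passed (camera adjusted p = 0.0251). Without knockout replicate 2, 5 genes of the macrophage list rose, and 1 fell without wild type replicate 3, knockout replicate 2 or knockout replicate 3. This list passed in the lower direction without knockout replicate 1 (camera adjusted p = 0.0380) and, relative to other genes only, with library totals (0.0458; mean log2 fold change 0.27). Mast cell genes had 4 tested members and no list test, and 0 of them passed by edgeR over all genes, adjusted over the list alone, by DESeq2, by limma-voom or at an unadjusted p under 0.05 (median 0.27, 0.073 to 0.42 without single libraries).

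**Figure D3:**
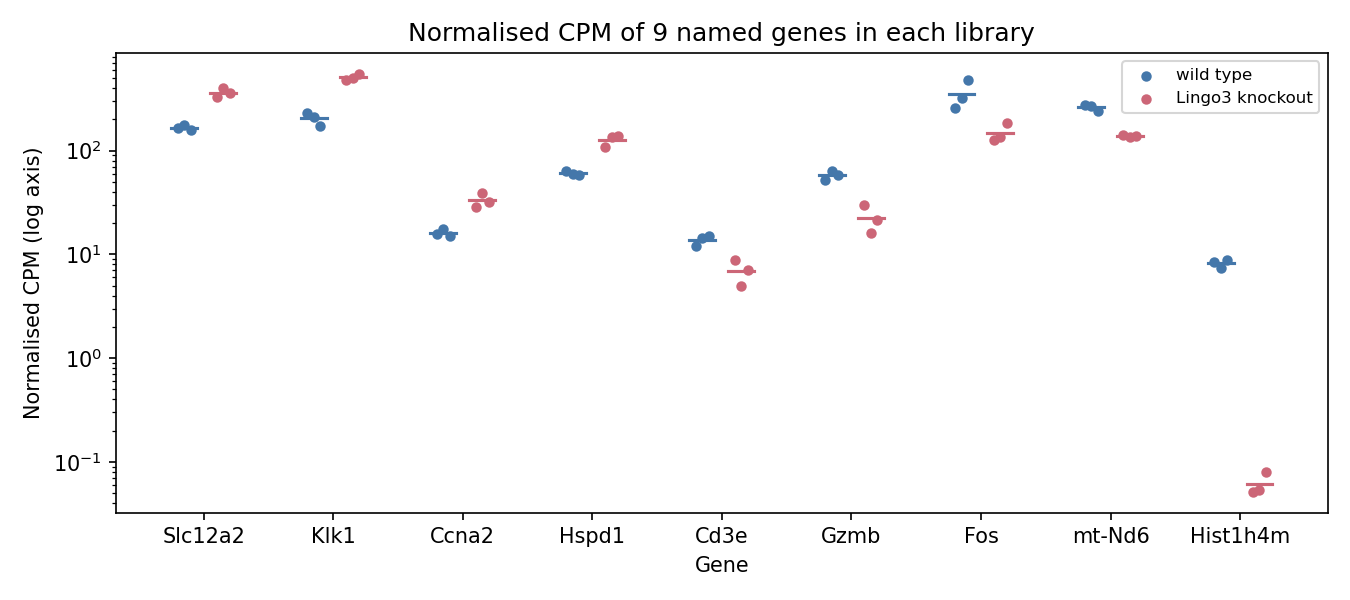
Normalised CPM of 9 named genes in each library on a log axis, wild type in blue and Lingo3 knockout in red, with a horizontal bar at the mean of each group (n = 3). Slc12a2, Klk1, Ccna2 and Hspd1 were higher in every knockout library than in every wild type library, and Cd3e, Gzmb, Fos, mt-Nd6 and Hist1h4m were lower.

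The fibroblast and smooth muscle lists passed the camera test in the lower direction, and those of endothelium, of neurons and glia and of red blood cells did not pass with all libraries. Of 20 fibroblast genes, 0 rose, 3 fell and 17 did not pass, and adjusted over the list alone 3 fell (median -1.06, camera adjusted p = 0.000143, and adjusted p = 0.556 with an estimated correlation). These were Thy1 (-1.24), which T cells also express, and the matrix genes Dpt (-1.49) and Postn (-1.46). Thy1 lost its call without wild type replicates 1 or 2 or knockout replicate 3 (highest edgeR adjusted p = 0.0714), Dpt without any 1 of wild type replicates 1, 2 and 3 or knockout replicates 2 and 3 (0.103), and Postn without any 1 of the knockout replicates 1, 2 and 3 (0.118). The fibroblast genes that fell were 10 without wild type replicate 3, 1 without knockout replicate 2 and 0 without wild type replicate 1, wild type replicate 2 or knockout replicate 3. Of 11 smooth muscle genes, 0 rose, 4 fell and 7 did not pass, and adjusted over the list alone 6 fell (median -0.52, camera adjusted p = 0.00412, and adjusted p = 0.450 with an estimated correlation). The tropomyosin gene Tpm2 fell by 0.70. The smooth muscle median was -0.32 without wild type replicate 2. The smooth muscle genes that fell were 2 without wild type replicate 1 and 1 without wild type replicate 2, knockout replicate 2 or knockout replicate 3. Of 10 endothelial genes, 0 rose, 2 fell and 8 did not pass, and adjusted over the list alone 2 fell (median -0.52, camera adjusted p = 0.133). The endothelial list passed without wild type replicate 3 (camera adjusted p = 0.0155) and with library totals only (0.0151). In the endothelial list 4 genes fell without wild type replicate 3. With all libraries the genes that fell were the receptor gene Kdr (-1.39) and the adhesion molecule gene Pecam1 (-0.99). Of 7 neuronal and glial genes, 0 rose, 1 fell and 6 did not pass, and adjusted over the list alone 1 fell (median -0.23, -0.37 to -0.051 without single libraries, or 0.06 with library totals only; camera adjusted p = 0.340). This was Snap25 (-0.80), whose call was lost without wild type replicates 1 or 2 or knockout replicates 1 or 2 (highest edgeR adjusted p = 0.130). Of 7 red blood cell genes, 0 passed over all genes, adjusted over the list alone, by DESeq2, by limma-voom or at an unadjusted p under 0.05 (median 0.53, 0.083 to 0.83 without single libraries, camera adjusted p = 0.163), and the list passed in the higher direction without knockout replicate 3 (camera adjusted p = 0.00651). The only tested sex-linked gene, Xist, did not pass (-0.20, or 0.08 with library totals only; edgeR adjusted p = 0.366).

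Changed genes of the mitochondrial genome were lower and changed nuclear genes of oxidative phosphorylation were higher. In the same libraries the mitochondrial share of counts, most of it ribosomal RNA, was 46.8% in wild type and 35.5% in knockout. Of 9 tested mitochondrially encoded genes, 0 rose, 5 fell and 4 did not pass, and adjusted over the list alone 8 fell (median -0.66, camera adjusted p = 0.000767, and adjusted p = 0.450 with an estimated correlation). The complex I subunit gene mt-Nd6 fell from 262 ± 18.9 to 139 ± 2.64 CPM (SD, n = 3), a log2 fold change of -0.91 ± 0.10 (SE; edgeR adjusted p = 0.000785), and mt-Nd5 had a log2 fold change of -0.75. These neighbours lie on opposite strands, and the strand setting of the counting is not given in the sources used here. Of 45 nuclear oxidative phosphorylation genes, 18 rose, 0 fell and 27 did not pass, and adjusted over the list alone 25 rose and 1 fell (median 0.29, camera adjusted p = 1.55e-07, and adjusted p = 0.556 with an estimated correlation). Without knockout replicate 3, 9 of these rose and 1 fell. The ATP synthase beta subunit gene Atp5b rose by 0.79 and the complex II gene Sdhc by 0.75. Of 74 cytosolic ribosomal protein genes, 17 rose, 0 fell and 57 did not pass, and adjusted over the list alone 19 rose and 1 fell (median 0.09, camera adjusted p = 0.00116, and adjusted p = 0.696 with an estimated correlation). Rps2 rose by 0.84 and Rpl4 by 0.72, values that are uncertain because ribosomal protein genes have many near-identical pseudogenes. The ribosomal protein median was 0.16 without knockout replicate 1 and 0.034 without knockout replicate 3. The ribosomal protein genes that rose were 10 without knockout replicate 3 and 11 without knockout replicate 2 or wild type replicate 3. Of 25 genes of fatty acid oxidation and PPAR signalling, 7 rose, 1 fell and 17 did not pass, and adjusted over the list alone 9 rose and 1 fell (median 0.27, camera adjusted p = 0.0393, and adjusted p = 0.652 with an estimated correlation). Acot1 rose by 1.52 and Hadhb, a subunit of the trifunctional enzyme, by 0.48, while the carnitine carrier gene Slc25a20 fell by 0.35. Slc25a20 lost its call without wild type replicates 1 or 3 or any 1 of the knockout replicates (highest edgeR adjusted p = 0.151). The genes of this list that rose were 4 without wild type replicate 3 or knockout replicate 2 and 3 without knockout replicate 3. The list lost its call without wild type replicate 1 (median 0.16, camera adjusted p = 0.179), knockout replicate 1 (0.104) or knockout replicate 3 (0.133), and with library totals only (0.0799), a mean CPM of at least 1 (0.0739), thinned counts (0.0695), GC and length offsets (0.0874) or nuclear protein-coding genes only (0.101).

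Cholesterol synthesis, secretory chaperones and interferon-induced genes were further groups in which more members rose than fell. Of 25 cholesterol synthesis genes, 11 rose, 1 fell and 13 did not pass, and adjusted over the list alone 12 rose and 1 fell (median 0.32, camera adjusted p = 4.33e-05, and adjusted p = 0.534 with an estimated correlation). The demethylase gene Cyp51 rose by 0.62, and the farnesyl diphosphate synthase gene Fdps fell by 0.82, a call lost without wild type replicate 1 or knockout replicate 3 (highest edgeR adjusted p = 0.0698). The cholesterol genes that rose were 2 without knockout replicate 2 and 4 without wild type replicate 2, wild type replicate 3 or knockout replicate 3. Of 24 endoplasmic reticulum stress genes, 7 rose, 1 fell and 16 did not pass, and adjusted over the list alone 14 rose and 1 fell (median 0.33, camera adjusted p = 3.58e-05, and adjusted p = 0.450 with an estimated correlation). The protein disulfide isomerase gene Pdia6 rose by 0.76. The glutathione-degrading enzyme gene Chac1 fell by 0.97, a call lost without wild type replicates 1 or 2 or any 1 of the knockout replicates (highest edgeR adjusted p = 0.150). The stress genes that rose were 11 without wild type replicate 1 and 3 without knockout replicate 3. Of 34 interferon response genes, 8 rose, 0 fell and 26 did not pass, and adjusted over the list alone 12 rose (median 0.23, camera adjusted p = 0.000178, and adjusted p = 0.534 with an estimated correlation). Iigp1 rose by 1.44 and the antiviral GTPase gene Mx1 by 0.60, and the interferon response genes that rose were 4 without wild type replicate 1 or 3 and 5 without knockout replicate 2, with 1 lower without knockout replicate 1. The median of this list was 0.37 without wild type replicate 2 and 0.36 without knockout replicate 3. Of 19 antigen presentation genes, 0 rose, 1 fell and 18 did not pass, and adjusted over the list alone 1 fell (median -0.18, -0.23 to -0.051 without single libraries, or 0.11 with library totals only; camera adjusted p = 0.340). This was H2-Q1 (-0.73), a class I gene with close paralogs, whose count is therefore uncertain. Of 20 antimicrobial and host defence genes, 2 rose, 1 fell and 17 did not pass, with the same counts adjusted over the list alone (median -0.05, -0.12 to 0.07 without single libraries, or 0.24 with library totals only; mean 0.10, camera direction higher, adjusted p = 0.404). Itln1 and the antibody transporter gene Pigr rose by 1.89 and 0.69, and S100a9, a calprotectin subunit gene of neutrophils, fell by 2.74. S100a9 was left out of the largest decreases above because it missed a limit set for them, on mean CPM or on overlap of the groups. The size of its fall is therefore uncertain. In this list 1 gene rose without wild type replicate 2, knockout replicate 2 or knockout replicate 3, and 2 fell without wild type replicate 1 or knockout replicate 1. Pigr lost its call without wild type replicates 2 or 3 or knockout replicates 2 or 3 (highest edgeR adjusted p = 0.114). Of 34 xenobiotic metabolism genes, 5 rose, 3 fell and 26 did not pass, with the same counts adjusted over the list alone (median 0.01, -0.12 to 0.01 without single libraries, or -0.06 with upper-quartile factors; mean -0.03, camera direction lower, adjusted p = 0.886). The xenobiotic genes that fell were 5 without knockout replicate 1 and 1 without wild type replicate 2 or 3 or knockout replicate 2 or 3. The glutathione transferase gene Gstm1 rose by 0.99.

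The immediate early and heat shock genes, the clock genes and the histone genes were the remaining lists that passed the camera test in the lower direction. Of 25 immediate early and heat shock genes, 1 rose, 9 fell and 15 did not pass, and adjusted over the list alone 2 rose and 14 fell (median -0.70, camera adjusted p = 6.96e-06, and adjusted p = 0.450 with an estimated correlation). The nuclear receptor gene Nr4a1 (-1.56) and Fos (-1.26) fell, and the member that rose was the mitochondrial chaperonin gene Hspd1 (1.07). Fos lost its call without knockout replicate 2 (edgeR adjusted p = 0.0729), and without that library 4 genes of the list fell. Of 17 circadian clock genes, 0 rose, 4 fell and 13 did not pass, and adjusted over the list alone 6 fell (median -0.11, or 0.17 with library totals only; camera adjusted p = 0.0276, and adjusted p = 0.450 with an estimated correlation). The repressor gene Nr1d1 fell from 19.7 ± 5.07 to 8.59 ± 1.54 CPM (SD, n = 3), and Cry2 had a log2 fold change of -0.66. Without wild type replicate 2, knockout replicate 2 or knockout replicate 3, 2 clock genes fell in each case. The clock median was -0.057 without wild type replicate 3, -0.18 without wild type replicate 2, -0.17 without knockout replicate 1 and -0.22 without knockout replicate 3. The clock list lost its call without wild type replicate 3 (camera adjusted p = 0.0657) or knockout replicate 2 (0.0685) and with library totals only (0.0759). Of 27 replication-dependent histone genes, which do not include Hist1h4m, 0 rose and 0 fell by edgeR over all genes or adjusted over the list alone, 1 fell by DESeq2 and 1 by limma-voom, and 1 was higher and 6 lower at an unadjusted p under 0.05. The median of the histone list was -0.19, or 0.09 with library totals only (camera adjusted p = 0.0393, and adjusted p = 0.450 with an estimated correlation). The histone median was -0.10 without knockout replicate 1 and -0.11 without wild type replicate 3. Its call was lost without wild type replicate 2 (camera adjusted p = 0.111), wild type replicate 3 (0.0521) or knockout replicate 1 (0.115), and with library totals only (0.154) or GC and length offsets (0.283), and 1 histone gene fell without knockout replicate 1 or 3.

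Lists tied more directly to Lingo3 or to the epithelial barrier did not pass the camera test. Of 9 tested genes of the LINGO family and its Nogo receptor partners, 1 rose, 1 fell and 7 did not pass, with the same counts adjusted over the list alone (median -0.14, -0.18 to 0.014 without single libraries, or 0.14 with library totals only; camera adjusted p = 0.821). The neurotrophin receptor gene Ntrk2 rose by 1.14, and the chemokine receptor gene Cxcr4 fell by 1.41, a call lost without wild type replicates 2 or 3 or knockout replicates 2 or 3 (highest edgeR adjusted p = 0.146). Of 18 genomic neighbours of Lingo3, 1 rose, 1 fell and 16 did not pass, and adjusted over the list alone 0 rose and 1 fell (median 0.02, 0.016 to 0.089 without single libraries, or -0.05 with upper-quartile factors; mean -0.01, camera direction higher, adjusted p = 0.761). These were the peptidase gene Thop1 (0.42) and Gadd45b (-0.78), a stress-induced gene. Thop1 lost its call without wild type replicates 2 or 3 or any 1 of the knockout replicates (highest edgeR adjusted p = 0.155), and Gadd45b without wild type replicate 1 or knockout replicate 3 (0.0702). Without wild type replicate 1, 2 neighbours rose, and without knockout replicate 1, 2 fell. Of 17 genes of EGFR ligands, receptors and targets, 3 rose, 1 fell and 13 did not pass, with the same counts adjusted over the list alone (median 0.16, 0.053 to 0.22 without single libraries, camera adjusted p = 0.515). The transcription factor gene Etv4 rose by 0.93, and Erbb2, a receptor of the EGFR family, fell by 0.52, a call lost without wild type replicate 3 or knockout replicates 1 or 2 (highest edgeR adjusted p = 0.0940). In this list 2 genes fell without wild type replicate 1. Egfr itself had a log2 fold change of 0.31 (edgeR adjusted p = 0.0946) and passed without wild type replicate 1. Of 16 epithelial repair and fetal-like genes, 1 rose, 2 fell and 13 did not pass, with the same counts adjusted over the list alone (median 0.01, -0.11 to 0.068 without single libraries, or -0.06 with upper-quartile factors; mean -0.34, camera direction lower, adjusted p = 0.515). The prostaglandin synthase gene Ptgs2 fell by 1.27. Without wild type replicate 3, 4 genes of the repair list fell and 0 rose, without any 1 of the knockout replicates 1 fell and 0 rose, and without wild type replicate 2, 2 rose. The list passed in the lower direction without wild type replicate 3 (camera adjusted p = 0.0438). Of 27 junction and adhesion genes, 4 rose, 0 fell and 23 did not pass, with the same counts adjusted over the list alone (median 0.04, -0.015 to 0.14 without single libraries, or -0.03 with upper-quartile factors; camera adjusted p = 0.159). The junction genes that rose were 7 without wild type replicate 1, and 2 fell without knockout replicate 1. The junction list passed without wild type replicate 1 (camera adjusted p = 0.0168) or knockout replicate 2 (0.0236) and with library totals only (0.0112). Cldn2, a pore-forming claudin, rose by 0.88.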

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

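The alternatives chosen after seeing the data were the thinned counts, the offsets for GC content and length, the restriction to nuclear protein-coding genes and, for the list tests, the upper-quartile factors. The 2596 changed genes (1589 higher, 1007 lower) became 5835 (5415 higher, 420 lower) with library totals only, a scaling that by its construction leaves the difference in RNA composition in the fold changes. With no filter 1675 genes were lower. At an adjusted p under 0.1, a looser threshold, 3942 changed and 1697 were lower. With glmTreat, which tests against a 1.2-fold change, 861 changed, 497 higher and 364 lower. With 1 library left out, and so fewer samples, the counts ran from 1124 to 2686 changed, 711 to 1677 higher and 413 to 1070 lower. With DESeq2, limma-voom, RLE factors, a mean CPM of at least 1, thinned counts, GC and length offsets, and nuclear protein-coding genes only, 2252 to 2551 genes changed. Upper-quartile factors gave 2502, of which 1137 were higher and 1365 lower.

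The replicate block gave 2061 changed genes, 1193 higher and 868 lower, of which 1924 were also called without it. Libraries of the same number did not share their deviations from the group means (r across genes -0.01, -0.12 and -0.10), so no pairing by number was seen. With 3 libraries per group a weak pairing could go unseen.

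Of 38 gene lists, 19 passed with the preset correlation, 0 with an estimated correlation and 6 by fry; the cause was not tested. All 19 kept their call with RLE factors, upper-quartile factors and the replicate block, 18 with a mean CPM of at least 1 and with thinned counts, 17 with GC and length offsets, 15 with library totals only and 17 of 18 among nuclear protein-coding genes. For 5 lists that did not pass, the direction relative to other genes turned, and the cause was not tested. The mean log2 fold change of the small intestinal enterocyte list was 0.24 with library totals only, -0.083 with a mean CPM of at least 1, -0.064 with thinned counts and -0.075 among nuclear protein-coding genes, and -0.13 to 0.17 without single libraries. That of the xenobiotic list was -0.033, with the direction turned by fry, and -0.13 to 0.019 without single libraries. The LINGO family list stood at -0.082 with thinned counts and -0.20 to -0.090 without single libraries, the macrophage list at -0.50 to 0.21 without single libraries, and the genomic neighbours of Lingo3 at -0.040 among nuclear protein-coding genes.

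Of 111 genes followed, 64 kept their direction and their side of the threshold in every alternative that gave them a value, 46 lost or gained the call in at least 1, and 1, Tff3, which did not pass, changed sign (0.10 with library totals only, which by construction raised the median of all genes by 0.28). Of 104 followed genes past the threshold, 63 kept the call without any single library, 41 lost it in at least 1 such fit and 0 changed sign. Many followed genes were chosen after these fits were seen and lean towards kept calls, so the counts do not stand for all genes. Without knockout replicate 3, 72 of the 104 kept the call, against 1084 of all 2596 changed genes. Without knockout replicate 2, 74 of the 104 kept it, against 1306 of the 2596. With a whole alternative in place, 90 kept it with library totals only and with the replicate block, 96 with limma-voom, 100 with DESeq2 and 97 of 102 with thinned counts. The Lingo3 difference of -0.0379 CPM lay between -0.0418 and -0.0221 under the scalings and with no filter, and between -0.0660 and -0.00696 without single libraries. DESeq2, limma-voom, a mean CPM of at least 1 and the replicate block gave no value for it. Depth, with a floor of 3 counts at 0.113 to 0.240 CPM, limited what could be said of Lingo3 and Tff1.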

Other observations

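The lists in this paragraph were assembled after the data were seen, so their counts describe the libraries and test nothing. Genes that rose in the knockout libraries were 13 of 25 genes of ribosome biogenesis (median log2 fold change 0.42), 9 of 19 aminoacyl-tRNA synthetase genes (0.37), 11 of 21 genes of mitochondrial import and chaperones (0.40) and 8 of 15 genes of one-carbon and serine metabolism (0.46), with 0 lower in each by edgeR. At an adjusted p under 0.05 without knockout replicate 2, 5 synthetase genes and 7 import genes rose, and without knockout replicate 3, 6 import genes rose. Of 12 pan-epithelial genes 2 rose and 0 fell (median 0.22), with 4 higher without wild type replicate 1 and 1 without knockout replicate 3. With library totals only, which raised the median of all genes by 0.28, the genes that rose were 25 of ribosome biogenesis, 19 synthetase, 18 import, 12 one-carbon and 10 pan-epithelial genes.

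Further sets of genes that lymphocytes express were lower as well, and these too were gathered after the data were seen. The T cell receptor segments overlap the fixed T cell list, which holds receptor constant genes, so they are not a separate set of genes. Of 8 genes of the GIMAP family, GTPases of lymphocytes, 7 were lower and 0 higher (median -1.10), as were 11 of 17 T cell receptor segments (median -1.01), of which 7 were lower without wild type replicate 2 or 3 or knockout replicate 2 or 3. Of 8 complement and marker genes of resident macrophages, 1 rose and 0 fell (median 0.90). This median was 0.07 without knockout replicate 1, the library in which C1qa was at 8.65 CPM, against 2.49 and 4.16 CPM in knockout replicates 2 and 3, and 4 of these genes rose without knockout replicate 2. Among short noncoding RNAs, 14 of 102 snoRNA genes were lower and 1 higher (median -0.45, or -0.17 with library totals only), with 6 lower without knockout replicate 3 and 3 higher without wild type replicate 3.

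Of the tests below, only the splits were chosen before the data were seen. The thinning and the GC and length offsets were added after the data had been seen but before their own values were, and those of unequal loss between cell types, of the scaling, of short noncoding RNA and of Hist1h4m were chosen after the results they measure had been seen. The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 2596 changed genes, 1589 higher and 1007 lower, against 0 of each as the highest of the others, so that 1 of the 10 splits gave as many, and 19 lists past the preset camera test against 17, again with 1 as large. Every other division mixed the genotypes on both sides, so a difference between them would add to the spread within each side and lower the number of gene calls. The 0 calls therefore do not measure how many calls chance alone would give.

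The lower T cell transcripts of the knockout libraries were weighed first. Lower depth is argued against as the whole cause: after thinning every library to the smallest total, 23 of the 23 T cell list genes called lower were called lower. GC content and transcript length are argued against in the same way, with 22 of 23 called lower with offsets for both. A smaller share of every non-epithelial cell type alike is argued against by the macrophage list, which stood above the T cell list by 1.01 on the log2 scale (interval 0.136 to 1.89, adjusted for 7 lists), although for the other 6 lists the interval of this gap included 0, and the mean of the macrophage list itself ran from -0.50 without knockout replicate 1 to 0.21 without knockout replicate 2. A fraction with fewer lymphocytes, whether from the genotype or from how much of the mucosa was washed off, may explain the pattern and was not tested.

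The mitochondrially encoded transcripts were lower in the knockout libraries, and the composition factors as its only source are argued against: with library totals only the median of the 9 tested genes was -0.37 and all 9 were negative, from -0.88 to -0.12. These values restate the lower share of counts, and a share cannot show whether the amount per cell fell. Most of the mitochondrial share was ribosomal RNA, and how completely ribosomal RNA was depleted in each library was not tested. Differences in handling or library preparation between the groups cannot be told apart from an effect of genotype, since the labels name no preparation batch. Short noncoding RNAs were lower as well (median -0.37, 236 genes, or -0.086 with library totals only), with a median of -0.45 to -0.29 without single libraries. The bootstrap standard error of this median, 0.0506, came from resampling genes and not libraries, so it leaves out the spread between samples. A lower content of mitochondrial RNA in cells of a possibly more proliferative fraction remains open as a biological explanation and was not tested. Whether the fraction was more proliferative is itself not settled. Of 30 cell cycle genes 20 rose, but Mki67 did not pass (log2 fold change 0.17, edgeR adjusted p = 0.379).

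Hist1h4m was nearly absent from the knockout libraries. Its place on chromosome 13 argues against DNA around Lingo3, on chromosome 10, that could have been carried over from another strain, and within 10 Mb of Lingo3 36 of 232 genes (15.5%) changed, against 15.4% elsewhere. Reads assigned to other histone H4 genes in the knockout cannot be told apart from a loss of the transcript: the summed level of the 12 others differed by -65.3 CPM (standard error 29.3), and this spread would hide the 8.14 CPM that Hist1h4m lost. A variant or deletion at the locus that differs between the mouse lines may explain it and was not tested.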
